A study of Homo sapiens with 4 samples.

How the data were processed

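ChIP-seq of Flag-tagged HOXC10 in transfected MKN45 cells gave 3 ChIP libraries (replicates 1, 3 and 4 in the titles), and 1 input DNA sample completed the series. Groups were taken from the sample titles. No values of the input DNA sample were analysed here, and no ChIP library numbered 2 was analysed here. The submitters' processing notes name bcl2fastq, Trimmomatic 0.36, FastQC, Bowtie2 2.2.5, MACS2 and HOMER, without their roles, and the build hg19. The peak lists have the column names of a MACS2 table, and each list holds the peaks of a single library. The caller's settings, the control used and the read totals are not given in the sources used here.

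Each peak has values made by the authors. Positions, widths and summits are in hg19 base pairs, per the file headers. The signal column is the fragment pileup at the summit, per the file headers. The deposited −log10 p and −log10 q values are per peak, and every q-value in the authors' lists is under 0.05. The fold column is a ratio of pileup to local background made by the authors' caller, and is used only to describe and rank peaks within a list. From the values, the fold was read as (pileup + 1) over (local background + 1), and the local background was computed back from this. The pileup moved in whole steps of 1 in libraries 1 and 3 and in steps of 0.896 in library 4. Many of the local backgrounds were multiples of 0.873 in library 1, 0.853 in library 3 and 1.0 in library 4. Such steps are left when a caller scales the larger of the ChIP and control samples down, and give no read totals. Depth per library is therefore unknown as a read total. For libraries 1 and 3, whose backgrounds rank alike (rho 0.986), the background step of library 3 was 0.978 times that of library 1 and its lowest local background 0.945 times. Read as scaling to the same control, this puts both libraries at nearly the same depth, while library 3 held 0.412 times as many peaks. No such comparison was made for library 4, whose background differs. The deposited common table holds positions in hg19, a region class, and an assigned gene and transcript. Each of its 17928 regions is identical to a stretch covered in all 3 lists with list positions taken as half-open, which was checked for every row. The tool behind the annotation is not stated.

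Overlap was counted at 1 bp or more on chromosomes 1 to 22 and X, which hold 17896 common regions, and compared with 1000 circular shifts within chromosomes (seed 20, one-sided permutation test). Alternatives were a −log10 q of at least 5, equal numbers of peaks by −log10 p, 50% overlap of the shorter peak, summits within 100 bp, shifts of 10 to 100 kb, and leaving out each library. Rank agreement was Spearman's rho of the fold across common regions, with −log10 p and pileup as alternatives. A region takes the values of the peak of each library that contains it, and regions were ranked by the lowest of the 3 within-library percentiles of the fold. These values belong to the summit of the whole peak, which can lie outside the region. Library 1 peaks holding a common region had a median width of 632 bp, against 236 bp for the common regions. Windows of 5 Mb, with 1 Mb as the alternative, were used for the density of peaks, over windows with peaks in all 3 libraries. A chromosome end was its first window, where peaks start within it, and its last window, with the window before it where the last one was shorter than 50% of a window. The ratio of medians has a bootstrap interval over windows.

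The common table gives no distance to a transcription start site, so the upstream and 5′ UTR classes replaced the 5 kb distance chosen earlier. Gene assignments are the authors'. The hg19 annotation was not used here, and the RefSeq gene table used (GRCh38.p14) is of another build. It served only for names, neighbours and the list of 19974 protein-coding genes, and gene lengths were not taken from it. The test of gene lists was therefore Fisher's exact test without length strata. Of 9008 gene identifiers on chromosomes 1 to 22 and X, 8670 were in that table and 6997 were protein-coding. The 16 lists were the HOX clusters, HOX cofactors, NF-kB, WNT, TGF-beta and BMP, receptor kinase and MAPK, adhesion and epithelial-mesenchymal transition, gastric and intestinal epithelium, angiogenesis and hypoxia, cell cycle, DNA damage and p53, immediate early genes, and the control lists ribosomal proteins, olfactory receptors, neuronal genes and muscle genes. The lists, the tests and the main alternatives were fixed before the data were examined. Lists were counted near start sites first. Counting any class but intergenic, or the upstream class alone, was added after seeing the data, as were the shifts of 10 to 100 kb for pairs of libraries, the ranking by pileup, the class test ranked by −log10 p, and the checks of the any-class counts.

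Named genes followed a rule fixed beforehand: genes assigned to the 15 highest ranked regions, to the 15 highest ranked near start sites, and up to 4 members of each list with a region near a start site, with HOXC10 and MET always looked at. A list's genes beyond these are named where its count is 5 or fewer, some members are not reported here, and other HOX genes with common regions were named after their values were seen. Motif searches, distances of 1 kb and 50 kb, and comparison of region classes with shifted regions need the hg19 sequence or annotation and were not run. Every column of values was matched to its sample or to the group.

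Wilson intervals are at the 95% level, and adjusted p-values use Benjamini-Hochberg over the 16 lists with a threshold of 0.05. Peaks and regions are not replicates, so p-values over them describe these libraries. The overlap count was tested on simulated data, where 1998 planted regions among 392190 simulated peaks gave 1969 above chance. Simulated peaks were placed at random along each chromosome, without the crowding of the real peaks. This checks the counting and not whether shifts suit crowded peaks. For the pairwise share, 0 of 20 shifted lists without sharing had a p under 0.05. These lists were themselves made by shifting, like the chance lists. They therefore cannot show whether shifts are a fair measure of chance for crowded peaks. In simulated lists of 36 genes with a 30% against a 5% share, the list test called 92.5% at a p under 0.05/16. Smaller differences, such as the 13.2% against 4.86% observed for receptor kinase genes near start sites, were not simulated. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.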

Results

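HOXC10, a homeobox transcription factor of the HOXC cluster, was expressed with a Flag tag from a plasmid in MKN45, a human gastric cancer cell line known for its amplified MET gene. Chromatin bound by the tagged protein was collected with an anti-Flag antibody 48 hours after transfection and sequenced (ChIP-seq). The series held 3 HOXC10-Flag ChIP libraries, numbered 1, 3 and 4 in the labels, and 1 input DNA sample. The authors' peak list of each ChIP library and their annotated table of regions common to the 3 lists were analysed. The labels do not say whether the 3 libraries came from separate transfections. The protocol also names an empty-vector transfection, and neither an empty-vector library nor the input signal was analysed here. Peaks are therefore places called by the authors over their own background, with no comparison to cells lacking the tagged protein. Read totals per library are unknown, because the peak lists carry none.

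The 3 lists differed in length. Library 1 held 254921 peaks, library 3 held 105092 and library 4 held 47789, and the peaks covered 128.8 Mb, 51.8 Mb and 13.9 Mb of chromosomes 1 to 22 and X. The median peak was 361 bp wide in library 1, 358 bp in library 3 and 259 bp in library 4. Fold enrichment, the authors' own value for each peak, had a median of 5.15 in library 1 (interquartile range 4.15 to 6.38), 5.80 in library 3 (4.58 to 7.45) and 4.22 in library 4 (3.43 to 4.97). The highest fold was 29.0, 21.5 and 12.3, respectively.

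The first question was whether the 3 libraries marked the same places in the genome. On chromosomes 1 to 22 and X, 17896 regions were covered by a peak in every library, against a mean of 123 (SD 24.0) in 1000 circular shifts of the lists along the chromosomes (one-sided permutation test, p = 0.001, the smallest these shifts can give). Shifts of only 10 to 100 kb, which keep the local crowding of peaks, gave a mean of 1357 regions. In both kinds of shift libraries 1 and 3 were moved separately, so their overlap with each other was lost as well. The common regions lay in 6.55% of the library 1 peaks, 16% of the library 3 peaks and 36.7% of the library 4 peaks. Of the library 3 peaks, 93.3% overlapped a library 1 peak, where circular shifts gave 9.57% and shifts of 10 to 100 kb gave 29.2%. Library 4 peaks overlapped a library 1 peak in 75.1% of cases (shifts 7.36% and 16.2%) and a library 3 peak in 38.9% (shifts 3.01% and 7.21%). The number of common regions depended on the threshold and on each of libraries 3 and 4. It was 4676 at a −log10 q of at least 5 in each library, 4809 with equal numbers of the strongest peaks, 36289 without library 3 and 105445 without library 4. With equal numbers, the pairwise shares were 38.3% for libraries 1 and 3, 24.3% for 1 and 4, and 23.9% for 3 and 4.

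**Figure D1:**
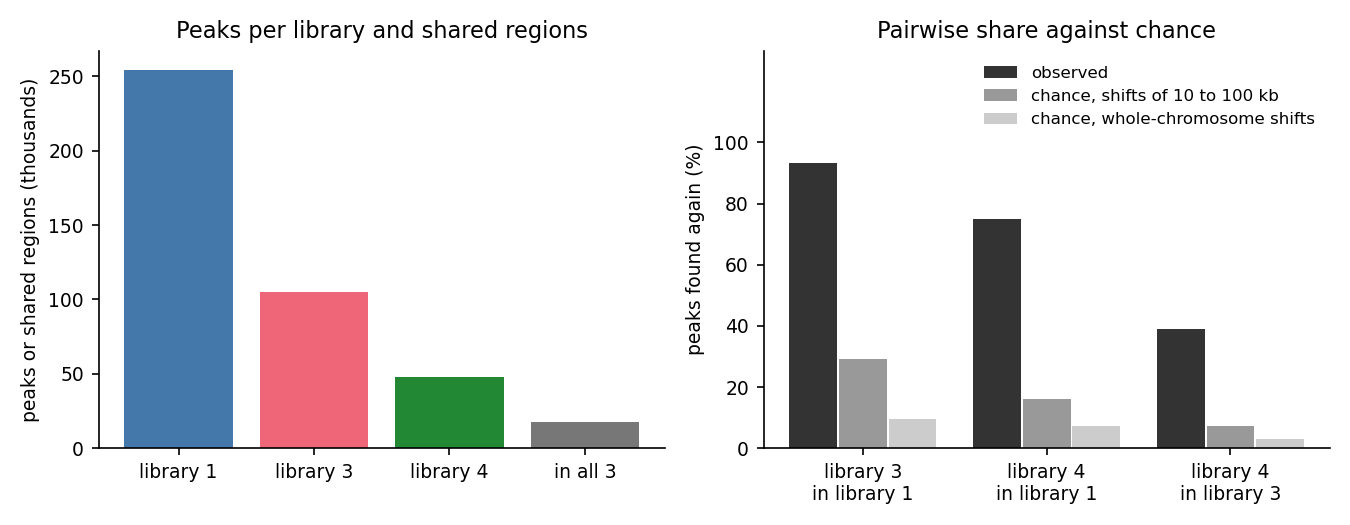
Left, the bars give the number of peaks on chromosomes 1 to 22 and X in each library and of regions covered in all 3 (in units of 1000). Right, the bars give the percentage of peaks of the first-named library that overlapped a peak of the second, observed and as the mean of 1000 shifts of each kind; the observed shares of 93.3%, 75.1% and 38.9% all lie above both chance values.

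Regions with a high fold in one library did not generally have a high fold in another. Across the 17896 regions, Spearman's rho of the fold was 0.28 between libraries 1 and 3, 0.02 between 1 and 4 and 0.03 between 3 and 4. These are correlations across regions, which are not independent replicates. Summit pileup, the fragment coverage at the peak's highest point, was more alike, with rho of 0.53, 0.56 and 0.39 for the same pairs. Given the local backgrounds of both libraries, these fell to partial rho of 0.168, 0.229 and 0.0991. The background was computed from pileup and fold, so this fall is tied to the low agreement in fold. Libraries 1 and 3 had nearly the same ranks of background, which divides the fold (rho 0.986 at summits within 5 bp). With library 4 this rho was 0.477 for library 1 and 0.427 for library 3. The 0.28 and the larger overlap of libraries 1 and 3 therefore cannot be read as closer agreement in binding. Peaks of library 4 that held a common region had a median fold of 3.61 against 4.51 for its other peaks. In library 1 these medians were 5.42 and 5.13, and in library 3 they were 6.24 and 5.77. Of the lowest 10% of library 4 peaks by fold, 68.0% were found in all 3 libraries, against 16.6% of the highest 10%. The same shares rose from 8.76% to 11.9% in library 1 and from 12.7% to 23.8% in library 3. The strongest peaks of library 4 were thus found again less often than its weakest.

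The regions that ranked highest in all 3 libraries were assigned to genes of varied function, and 9 of the 15 lay in intergenic sequence at distances the table does not give. The highest ranked region was in an exon of XYLT1, which encodes the xylosyltransferase that starts glycosaminoglycan chains (chromosome 16, 17202490 to 17202817, hg19), with folds of 11.6, 14.0 and 7.38 in libraries 1, 3 and 4. It was followed by an intron of PROX1-AS1, the antisense RNA of the PROX1 homeobox locus (chromosome 1, 214158735 to 214159033; 10.2, 13 and 7.24). An intron of CLEC16A, a regulator of mitophagy, came next (chromosome 16, 11097047 to 11097280; 10.2, 14.4 and 8.40). Further regions among the 15 highest ranked lay in an intron of SLC12A2, the sodium, potassium and chloride cotransporter NKCC1 (chromosome 5, 127444894 to 127445189; 9.57, 12.4 and 6.91), and in an exon of SYNJ1, a phosphoinositide phosphatase (chromosome 21, 34017945 to 34018168; 9.45, 14.3 and 6.82). An intron of RNF11, a RING finger protein gene, was also among them (chromosome 1, 51716434 to 51716720; 10.6, 10.7 and 7.10). Intergenic regions assigned to UBASH3B, C3orf58, GRB10, KLHL4 and CDH12 were in the same group. The region assigned to CDH12, a cadherin gene, had the highest library 4 fold of the 15 (chromosome 5, 22902052 to 22902451; 12.7, 10.7 and 9.29). Regions assigned to FAM27L, ANKRD30BP3, YY1P2 and LOC285593 completed the 15. FAM27L, ANKRD30BP3 and YY1P2 belong to families with close copies or are pseudogenes, so their assignment is uncertain. None of the 15 was in the upstream or 5′ UTR class. For XYLT1, SLC12A2, FAM27L, ANKRD30BP3, YY1P2 and LOC285593, the local background was the lowest of the list in libraries 1 and 3 (1.51 and 1.42). Of all peaks, 23.8% in library 1 and 13.5% in library 3 stood at this lowest value. The other regions of the 15 had a higher background in library 1. A ranking by fold can favour places of low background.

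Most common regions lay in introns or between genes. Of the 17928 regions in the authors' table, introns held 6913 (38.6%, Wilson 95% interval 37.8 to 39.3), intergenic sequence 6503 (36.3%, 35.6 to 37.0) and exons 2693 (15.0%, 14.5 to 15.6). The upstream class held 666 regions (3.71%, 3.45 to 4.0), 5′ UTRs 607 (3.39%, 3.13 to 3.66), 3′ UTRs 351 (1.96%, 1.77 to 2.17) and the downstream class 195 (1.09%, 0.946 to 1.25). These intervals cover counting error only. The share of the genome in each class was not measured here, so no class can be called favoured or avoided. Upstream and 5′ UTR regions, taken here as near a transcription start site, made up 1273 of the 17896 regions on chromosomes 1 to 22 and X (7.11%, 6.75 to 7.50), or 3.72% with the upstream class alone. They were less frequent among the higher ranked than among the lower ranked 50% of regions by fold, at 5.60% against 8.63% (odds ratio 0.628, two-sided Fisher's exact test over regions, p = 3.29e-15). The caller's local background was also higher near start sites, with a median of 5.24 against 3.49 elsewhere in library 1 and 5.12 against 3.41 in library 3, but not in library 4 (4.43 against 4.47).

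The highest ranked regions near start sites belonged to genes of varied function. The 5′ UTR of EPHA3, an ephrin receptor (chromosome 3, 89156528 to 89156824), had folds of 7.05, 11 and 6.46 in libraries 1, 3 and 4. The 5′ UTR of APBB1, an adaptor that binds the amyloid precursor protein (chromosome 11, 6426519 to 6426817), had folds of 9.11, 13.8 and 5.44. The 5′ UTR of PKIA, an inhibitor of protein kinase A (chromosome 8, 79428492 to 79428774), had 6.56, 13.3 and 6.01. Upstream of GALNT14, a transferase that starts mucin-type O-glycosylation (chromosome 2, 31361589 to 31361828), the folds were 8.74, 11.4 and 5.03. EVX1, the homeobox gene beside the HOXA cluster, had a 5′ UTR region (chromosome 7, 27284626 to 27284818) with folds of 8.12, 8.16 and 4.97. The same group held 5′ UTR regions of PDRG1, SCHIP1 and SLC45A3, and upstream regions of ADAM20, CCDC60, ILDR2 and C3orf67. It also held upstream regions assigned to LOC101928601, LOC101927313 and MIR5701-2, the last a microRNA gene with a near-identical copy and so uncertain.

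HOX genes themselves carried common regions in all 4 clusters. Outside intergenic sequence, 17 of the 39 HOX genes had 32 such regions, namely 6 of 11 HOXA genes, 1 of 10 HOXB genes, 5 of 9 HOXC genes and 5 of 9 HOXD genes. Of all protein-coding genes, 28.1% had such a region. The HOX share of 43.6% did not pass Fisher's exact test against other genes (adjusted p = 0.123). HOXA5 had 5 regions and HOXA3 had 4. Some of the HOXA5 regions lay within the same peak of library 1 or library 3, so they are not 5 separate sites in each library. An intron of HOXC4 (chromosome 12, 54445881 to 54446123) had folds of 6.63, 6.15 and 10.6 in libraries 1, 3 and 4, and an intron of HOXA7 (chromosome 7, 27195513 to 27195837) had 6.14, 7.41 and 4.99. Near start sites, 3 HOX genes had a region. HOXD8 had 2 in its 5′ UTR, at 176994984 to 176995177 (8.47, 7.93 and 3.82) and 176995305 to 176995534 (8.47, 7.93 and 3.25) on chromosome 2, within the same peaks of libraries 1 and 3. HOXA3 had one in its 5′ UTR (chromosome 7, 27150261 to 27150477; 3.70, 3.47 and 2.80), and HOXA2 had one upstream (chromosome 7, 27143228 to 27143475; 6.78, 9.40 and 2.34). At a −log10 q of at least 5 in each library, none of these start-site regions was left.

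**Figure D2:**
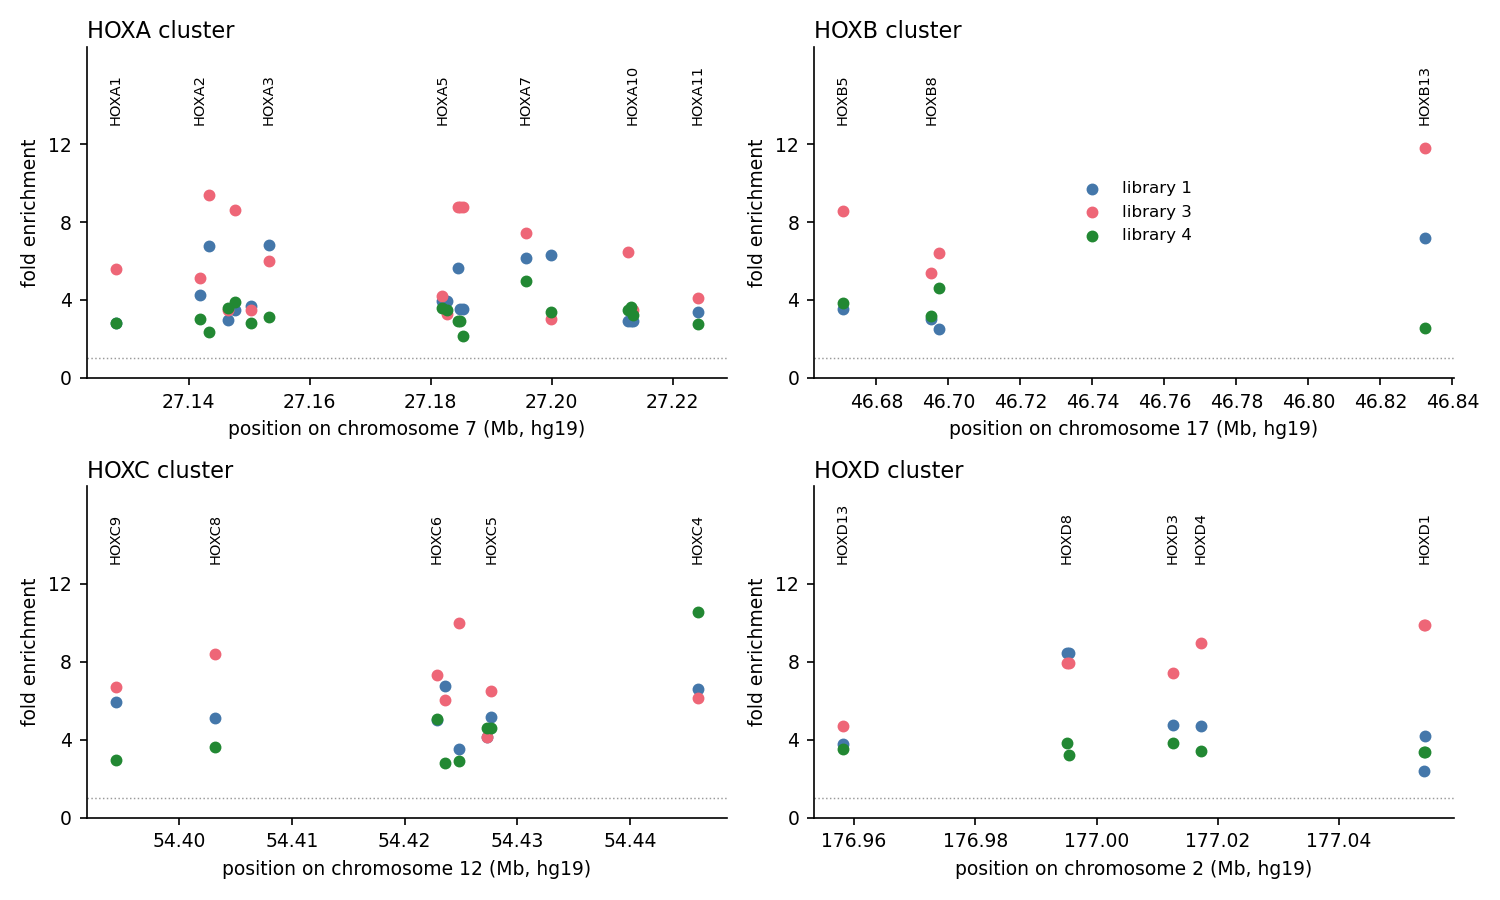
Common regions assigned to HOX genes in the 4 clusters, by hg19 position in Mb (horizontal) and the authors' fold enrichment of the overlapping peak in libraries 1, 3 and 4 (points); gene names stand above the highest ranked region of each gene, intergenic regions included, and the dotted line marks a fold of 1. The highest point in library 4 is the HOXC4 intron region, with a fold of 10.6.

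No common region was assigned to HOXC10, the transfected gene. Its place in the cluster, between HOXC11 and HOXC9, fell in a stretch of 33.5 kb without a common region, between a region assigned to HOTAIR, a long noncoding RNA of the HOXC cluster (chromosome 12, 54360445 to 54360761), and one in an exon of HOXC9 (54394225 to 54394544). That stretch held 14 peaks in library 1 with folds of up to 8.24, 8 peaks in library 3 with folds of up to 8.57, and 0 peaks in library 4. MET, the receptor tyrosine kinase gene amplified in this line, had 3 common regions of low rank. The 5′ UTR region (chromosome 7, 116312440 to 116312661) had folds of 4.53, 3.11 and 2.96, and the intron region (116353221 to 116353394) had 5.22, 3.80 and 3.37. The third region, in intergenic sequence (116278359 to 116278789), had folds of 2.19, 6.93 and 3.60.

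Gene groups were then compared for common regions near their start sites, in the upstream or 5′ UTR class. Of 19974 protein-coding genes, 970 (4.86%) had such a region. Of 42 WNT pathway genes, 5 did (11.9%, Fisher's exact p = 0.0515, adjusted p = 0.412): LGR5, the stem cell receptor for R-spondins, the kinase GSK3B, the ligands WNT1 and WNT5A, and the receptor FZD1. The LGR5 region, in the 5′ UTR (chromosome 12, 71833493 to 71833725), had folds of 7.02, 14.5 and 3.63. Of 38 receptor kinase and MAPK pathway genes, 5 did (13.2%, Fisher's exact p = 0.0356, adjusted p = 0.412), among them AKT2, PIK3R1, MET and MAPK9. The AKT2 region, in the 5′ UTR (chromosome 19, 40771971 to 40772317), had folds of 5.12, 11.1 and 4.43, and the PIK3R1 region, also in the 5′ UTR (chromosome 5, 67584305 to 67584509), had 3.53, 5.39 and 4.53. None of the 16 fixed lists passed Fisher's exact test (two-sided, Benjamini-Hochberg over the lists), and 1 had an unadjusted p under 0.05.

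The other lists had 0 to 3 genes with a region near a start site, given here with the adjusted p of the same test. By Fisher's exact test, the TGF-beta and BMP pathway had 3 of 34 genes (TGFB2, BMPR1A and SMAD1; 8.82%, adjusted p = 0.603), the HOX clusters 3 of 39 (7.69%, 0.699), and angiogenesis and hypoxia 3 of 24 (KDR, THBS1 and EGLN1; 12.5%, 0.579). Adhesion and epithelial-mesenchymal transition had 2 of 36 (the tight junction claudins CLDN7 and CLDN3; 5.56%, 0.879) and the cell cycle 2 of 39 (CCND2 and CDKN2C; 5.13%, 0.879). The NF-kB pathway had 1 of 30 (TRAF1; 3.33%, adjusted exact p = 1). No gene of 34 gastric and intestinal epithelium genes (0.699), 30 DNA damage and p53 genes (0.699), 20 immediate early genes (0.879) or 11 HOX cofactors (adjusted exact p = 1) had one. Among the control lists, neuronal genes had 3 of 36 (SLC17A7 and RBFOX1 among them; 8.33%, 0.603), muscle genes 1 of 34 (MYF5; 2.94%, adjusted exact p = 1), and ribosomal proteins and olfactory receptors 0 of 40 each (both 0.603).

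With any class but intergenic counted, a choice made after seeing the data, 5616 protein-coding genes (28.1%) had a common region and 5 lists differed from other genes by Fisher's exact test. WNT pathway genes were higher, with 25 of 42 (59.5%, Wilson interval 44.5 to 73.0, adjusted exact p = 0.00017), among them AXIN1 and WNT3A with 6 regions each. Receptor kinase and MAPK pathway genes were also higher, with 21 of 38 (55.3%, 39.7 to 69.9, adjusted exact p = 0.00179), among them MAP2K3 with 10 regions and EGFR with 4; MAP2K3 has close copies in the genome, so its count is uncertain. AXIN1, WNT3A, MAP2K3 and EGFR were named after their values were seen. The control list of neuronal genes was higher too, with 17 of 36 (47.2%, 32.0 to 63.0, adjusted exact p = 0.048). Ribosomal protein genes were lower, with 2 of 40 (5.0%, 1.38 to 16.5, adjusted exact p = 0.00179), as were olfactory receptor genes, with 0 of 40 (upper bound 8.76%, adjusted p = 4.99e-05). HOX genes at 43.6% (adjusted exact p = 0.123) and TGF-beta and BMP pathway genes at 44.1% (adjusted p = 0.123) did not pass. Neither did HOX cofactors (4 of 11), NF-kB (6 of 30), adhesion (13 of 36), gastric (8 of 34), angiogenesis (10 of 24), cell cycle (9 of 39), DNA damage (6 of 30), immediate early (4 of 20) and muscle genes (12 of 34). With intergenic regions included, 6 lists passed, as TGF-beta and BMP pathway genes then stood at 55.9% against 35% of all genes (adjusted exact p = 0.0474).

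These shares were not corrected for gene length, and a longer gene can hold a region more easily. No list passed when only regions with a −log10 q of at least 5 in each library were counted, where 9.11% of all genes had one. WNT pathway genes then stood at 11.9% (adjusted exact p = 0.77), receptor kinase genes at 15.8% (0.615) and neuronal genes at 25% (0.066, unadjusted 0.00412). Without regions in the 5 Mb at chromosome ends, 22 WNT, 20 receptor kinase, 17 HOX and 13 neuronal genes had a region, against 23% of all genes. Neuronal genes no longer passed (36.1%, adjusted exact p = 0.147) and HOX genes did (43.6%, 0.0128). Genes at the ends stay in these totals as genes without a region, and the number of HOX genes with a region was 17 in both settings, so no call is drawn from this one.

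**Figure D3:**
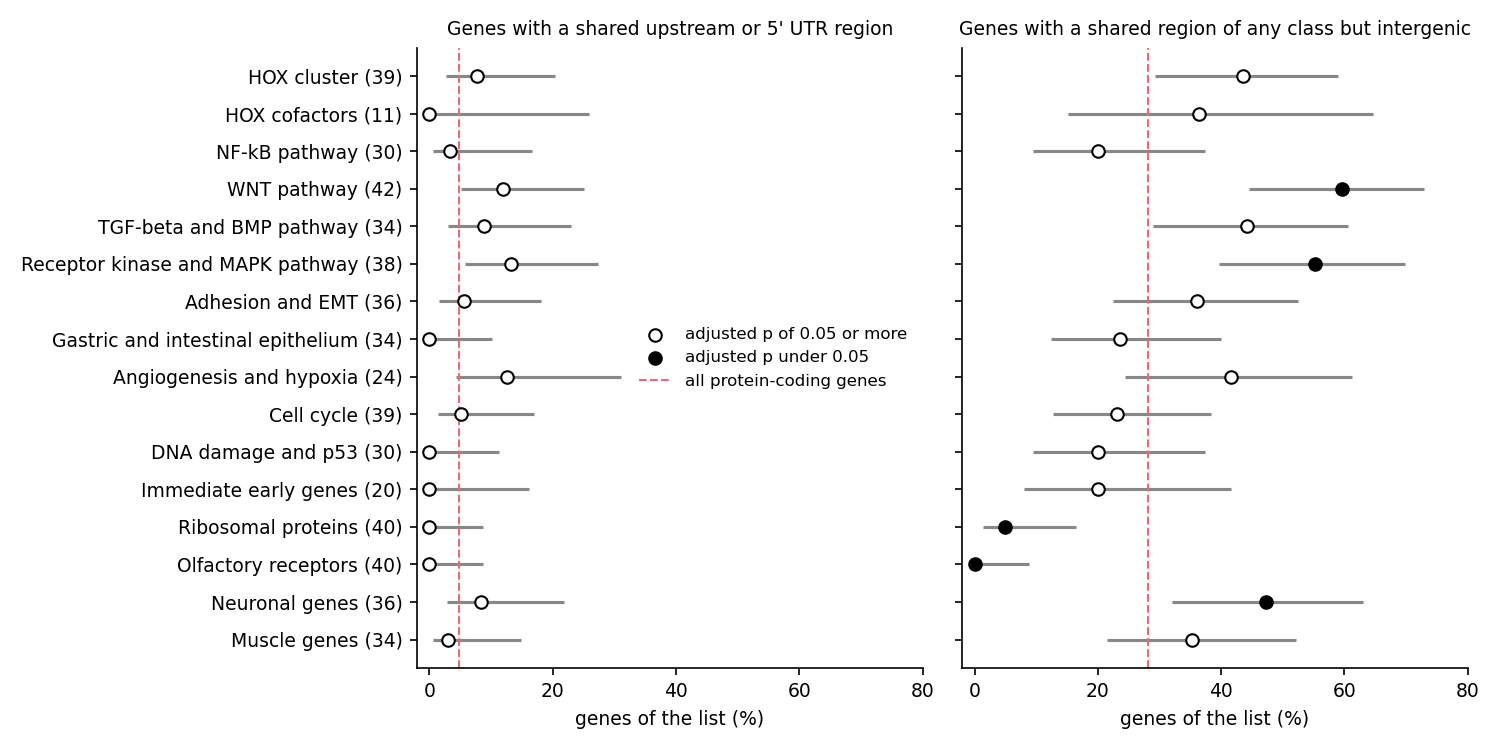
Percentage of each list's genes with a common region in the upstream or 5′ UTR class (left) and in any class but intergenic (right), with Wilson 95% intervals and the number of genes tested in parentheses; filled points have an adjusted p under 0.05. The dashed lines mark all protein-coding genes, at 4.86% and 28.1%, and filled points appear only on the right.

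Peaks were unevenly spread along the chromosomes. Of 599 windows of 5 Mb, 46 (7.68%) held over 3 times the library's median number of peaks in all 3 libraries, and 19 of the 46 lay at chromosome ends. Windows at the ends were 8.85% of all windows but held 22.4% of the library 1 peaks, 32.6% of the library 3 peaks, 18.6% of the library 4 peaks and 25.6% of the common regions. The median density at the ends was 327 peaks per Mb against 45.6 elsewhere in library 1, 170 against 15.4 in library 3 and 42.1 against 11 in library 4. The ratios were 7.18 (95% bootstrap interval over windows 4.78 to 8.35), 11 (6.12 to 13.9) and 3.83 (3.0 to 4.68). The first 5 Mb of chromosome 5 held 385 common regions, those of chromosome 7 held 304 and those of chromosome 11 held 275.

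**Figure D4:**
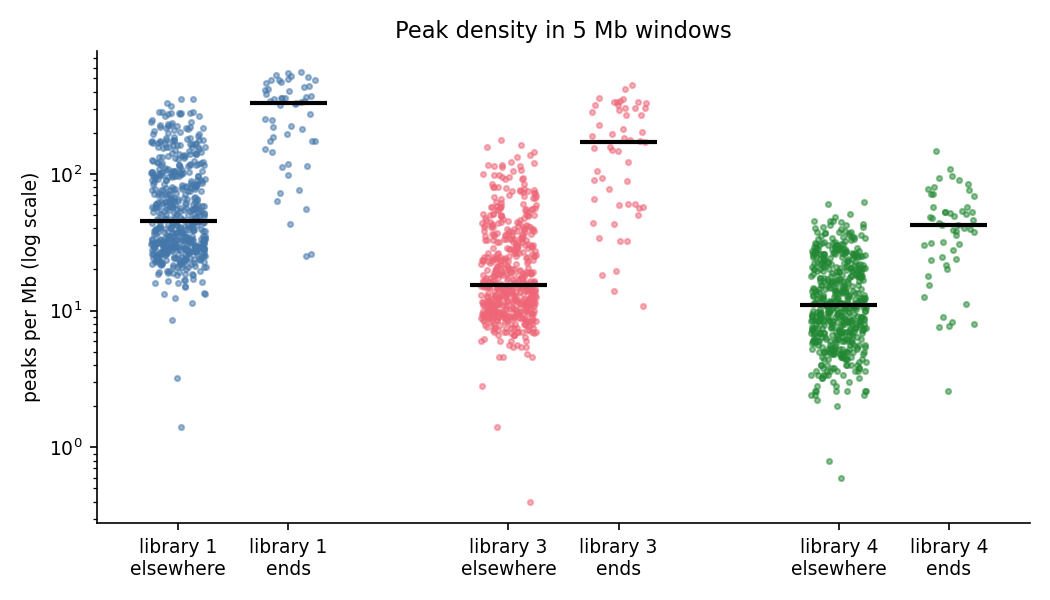
Peaks per Mb (vertical, log scale) in 5 Mb windows at chromosome ends and elsewhere, for libraries 1, 3 and 4; each point is a window with peaks in all 3 libraries and each bar a median. The medians at the ends lie above those elsewhere in every library, by ratios of 7.18, 11 and 3.83.

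Library 4 stood apart from the other libraries in its local background. At common regions whose summits lay within 5 bp of each other, the background of libraries 1 and 3 had a Spearman's rho of 0.986 (823 regions, across regions). Between libraries 1 and 4 it was 0.477 (689 regions, 95% interval 0.417 to 0.532) and between libraries 3 and 4 it was 0.427. The library 4 background was a median of 1.37 times that of library 1 at these regions, with 5th and 95th percentiles of 0.502 and 3.38.

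**Figure D5:**
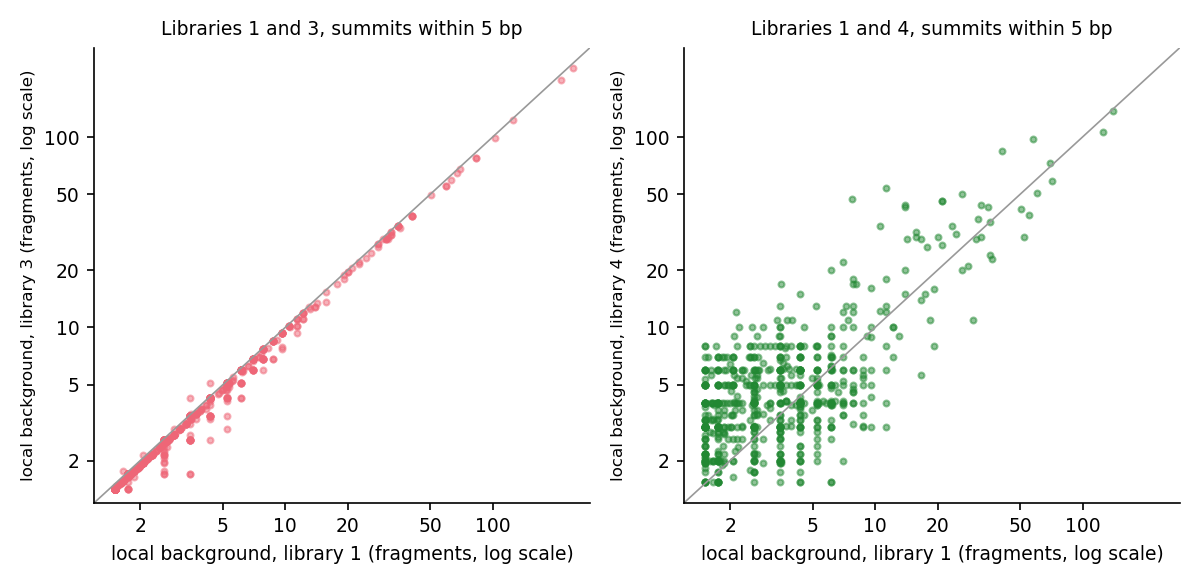
Local background back-computed from the authors' pileup and fold (fragments, log scales) at common regions with summits within 5 bp, library 1 against library 3 (left) and library 4 (right); each point is a region and the line marks equal values. The points follow the line closely on the left (rho 0.986) and scatter widely on the right (rho 0.477).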

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

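Counting upstream regions alone or any class, ranking by pileup, and the checks of the any-class counts were chosen after the results were seen. No paired analysis was possible because the input DNA carries no replicate number and no comparison between groups was made. The overlap of the lists stayed above chance in every alternative compared with shifts, and the higher share of start-site regions at low rank held at a −log10 q of at least 5 (odds ratio 0.418) and when ranked by −log10 p (0.827, Fisher's exact p = 0.00112). The number of common regions moved to 4676 at a −log10 q of at least 5, 4809 with equal numbers of peaks and 6211 with summits within 100 bp; leaving out a library gave 18737 to 105445, since fewer lists then have to overlap. Rank agreement of libraries 1 and 3 moved to 0.13 by −log10 p and 0.528 by pileup, that of 1 and 4 to 0.0621 and 0.564, and that of 3 and 4 to 0.385 by pileup. The share near start sites was 3.72% with upstream regions alone, since a class was left out. Windows of 1 Mb gave 10.6% dense windows against 7.68%.

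Of the lists near start sites, 5 passed once any class but intergenic was counted; for the lists in any class, 0 passed at a −log10 q of at least 5, where fewer regions remained, and 6 passed with intergenic regions included, TGF-beta genes being gained (55.9%, adjusted exact p = 0.0474). Without regions at chromosome ends 5 passed, with HOX genes gained (0.0128) at an unchanged count against a lower background, and neuronal genes lost (0.147). Several lists changed sides of the share of all genes, none of them past the threshold on either side; other causes were not tested. At a −log10 q of at least 5, HOX, WNT, TGF-beta, receptor kinase and cell cycle genes near start sites each fell to 0%, where 1.19% of all genes had a region. With upstream regions alone, NF-kB genes stood at 3.33% and angiogenesis genes at 0%, against 2.2%. With any class but intergenic, HOX cofactors stood at 36.4%, cell cycle genes at 23.1% and muscle genes at 35.3%, against 28.1%. Among any-class shares, gastric genes stood at 35.3% with intergenic regions included, against 35%, and NF-kB genes at 10.0% and angiogenesis genes at 8.33% at a −log10 q of at least 5, against 9.11%. Not run were the start-site distances of 1 kb and 50 kb, the motif alternatives, and leaving out a library for start sites and lists, since only regions common to all 3 libraries are annotated. The alternative without length strata is the reported test, the fixed fallback where gene lengths are missing. Unknown read totals limit the comparison of peak numbers with library 4.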

Other observations

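The test of whether the same control reads were scaled, and the division of the chromosome-end tests by library, were chosen after the results were seen.

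Genes of the gastric and intestinal epithelium had no common region near a start site, but 8 of 34 had one in another class outside intergenic sequence. Those named here were chosen after their values were seen. The mucin gene MUC6 had 5 regions outside intergenic sequence, MUC2 and MUC1 had 3 each, and HNF4A, a transcription factor of the gut epithelium, had 3. BARX1 had 2 regions, and GATA6 and VIL1 had 1 each. This share of 23.5% was not different from that of all genes (28.1%, Fisher's exact test, adjusted p = 0.703). Without regions in the 5 Mb at chromosome ends the gastric share was 17.6%, against 23% of all genes (adjusted Fisher's exact p = 0.671). Among the HOX cofactors, PBX3 and PKNOX2 had 2 regions each and MEIS3 had 1.

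Some genes were assigned many common regions, intergenic ones included, and these too were named after their values were seen. PTPRN2, a receptor-type phosphatase gene, had 87 regions between 157335434 and 158379768 on chromosome 7. MAD1L1, a spindle checkpoint gene, had 57 on the same chromosome between 1863151 and 2272447. TTC34 had 55 on chromosome 1, OSBPL5 had 50 on chromosome 11 and CDH4 had 41 on chromosome 20. Away from the chromosome ends, PLS3 had 43 between 114918056 and 115062649 on chromosome X. LOC100134317 had 42 between 36760715 and 36800562 on chromosome 19, and FCGR2A had 31 between 161410564 and 161450559 on chromosome 1. Whether such crowded regions lie within the assigned gene or in repeated sequence was not tested. The regions of PTPRN2, MAD1L1, TTC34 and OSBPL5, and part of those of CDH4, lie in windows at chromosome ends, where peaks of all 3 libraries were dense.

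Peaks crowded near chromosome ends in all 3 libraries. Control coverage and copies were not measured, since the local background is known only at called peaks. A higher local background at the peaks was argued against as the whole cause in libraries 1 and 3. Windows were put into 3 equal groups by local background. In the middle group, ends still held 8.32 times the peaks per Mb in library 1 (3.42 to 10.0, 14 end windows). In library 3 they held 16.7 times as many (9.24 to 22.9, 11 end windows). In library 4 the ratio of 2.85 rested on 7 end windows (0.82 to 3.92), so a higher local background stays open there. Control coverage or copies away from called peaks stay open in every library. Joining peaks closer than 10 kb cut the ratio from 11 to 1.68 (1.45 to 1.96) in library 3. In library 4 it fell from 3.83 to 2.58 (2.34 to 3.0). Broad stretches split into many peaks were therefore argued against as the whole cause in both. Peaks at the ends of libraries 1 and 3 lie closer than 10 kb on average, so joining lowers their ratio whatever the cause. How much of the library 3 excess came from split stretches therefore stays open, and the 0.8 of library 1 decides nothing. Base composition and gene density could contribute and were not tested, and neither was a biological explanation.

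Library 4 had another local background than libraries 1 and 3. The same control reads at another depth would leave the ranks nearly alike, but rho between libraries 1 and 4 was 0.477 (0.417 to 0.532) against 0.986 between 1 and 3. Slight shifts of the summit were argued against too, since at summits on the identical base rho was 0.521 (0.311 to 0.682, 62 regions). A candidate explanation that stays open is that library 4 was called against other control reads or with other settings, which no label states. No biological explanation was tested.

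Common regions were alike in pileup but not in fold. If places of high control coverage are called in every library, common peaks should have a high background at a given −log10 p, and in library 4 they did: in each of 5 bins of its peaks by −log10 p, the share found in all 3 libraries was at least 47.4 percentage points higher in the top than in the bottom quartile of background. In library 1 this difference was 6.79 to 18.1 points, and in library 3 it ran from -0.36 to 19.5 points, so places of high control coverage may account for part of the common peaks of library 4. At a given −log10 p a higher background also means a higher pileup, so real binding at well covered places stays open. A high background in every library went with much of the pileup agreement, but this is no separate test of a cause. The background was computed from the pileup and the fold, so at a given background pileup and fold rank alike. The fall in rho is therefore tied to the low agreement in fold. The rho of pileup fell from 0.564 to a partial rho, given both backgrounds, of 0.229 for libraries 1 and 4. It fell from 0.528 to 0.168 for 1 and 3, and from 0.385 to 0.0991 for 3 and 4. What remained for libraries 1 and 4 did not settle whether background was the whole cause, and no biological explanation was tested.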
